A study of Rattus norvegicus with 8 samples.

How the data were processed

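Lung RNA was hybridized to 8 two-channel arrays of 60-base probes, 1 array for each of 2 pretreatments (saline, cobalt) at each of 4 durations of hypobaric hypoxia. The labels give each array the 0 h RNA of the same pretreatment in the second channel. Hypoxia RNA was in Cy5 on the 4 saline arrays, which share slide 1, and in Cy3 on the 4 cobalt arrays, which share slide 2 and were scanned on another day. Pretreatment, slide, scan and dye orientation therefore cannot be told apart.

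Per the file headers, the scanner files were made with Agilent Feature Extraction 9.5.1.1 and hold mean signals and local backgrounds as intensity in scanner units. Per the file headers, the deposited LogRatio column is the log10 of red over green after the software's background subtraction and dye normalization. The deposited series matrix holds log2 ratios of hypoxia over 0 h, a scale and direction read from the values: against LogRatio the correlation was over 0.999 in size, positive on saline and negative on cobalt arrays, and every column has a median of 0.

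Each array has 45018 spots. Median signals were 73.9 to 92.8 in green and 110 to 163 in red, over backgrounds of 41.5 to 43 and 46.5 to 48. The coefficient of variation of replicate spots was 4.36% to 7.71% in green and 3.75% to 7.22% in red, and the spike-in slope was 0.880 to 0.980. The software marked 128 to 214 spots per array as outliers, which were dropped, and 120 to 232 red and up to 2 green signals as saturated, which were kept. Of 41012 probes, 10735 were named by accession, 5577 by symbol and 3730 by synonym from the gene names of the GRCr8 annotation, used for names only, and 20970 kept the name in the file. Of all of these, the probes that passed the filter below were tested.

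Signals were background-corrected by normexp (offset 50) and normalized by loess within arrays in limma 3.58.1 (R 4.3.3, the package data.table in version 1.17.8), with quantiles of mean intensity set equal between arrays for levels only. A probe was kept if well above background in either channel on at least 4 of the 8 arrays (28421 probes), and the probe with the highest mean intensity stood for each gene (24143 genes, 3476 with several probes, 236 with a saturated signal). Il6, well above background on at most 3 arrays, was too dim to be tested. Tnf was well above background on up to 5 arrays but did not pass the filter, which also drops probes with a missing value on any array. Mt2A was not found on the array. 2 genes that the naming rule selects are not reported here.

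With limma and a variance trend over mean intensity, the comparisons were hypoxia against 0 h for each pretreatment and for their average, cobalt response minus saline response, each duration, any difference between durations, 24 and 48 h against 6 and 12 h, the difference of that contrast between pretreatments, and the level of both channels together. A Benjamini-Hochberg adjusted p under 0.05 was called. Samples, comparisons, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The trend was first run over the mean log ratio by mistake; that version is kept as an alternative and was added after the data were seen. Labels do not say that arrays hold separate animals, so p-values measure spread between arrays and durations, and the spread of the 0 h RNA enters no p-value. In the 0 h channel, the arrays of a pretreatment correlated at 0.992 or more.

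The 35 gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry; list medians per array were set against 10000 random lists matched for intensity. Genes were named by rule: the 10 highest and 10 lowest estimates among named genes that passed with 1 sign on all arrays (for differences, without overlap), or the 3 with the lowest p where none passed; 2 to 4 members of each list with the lowest p; and 19 genes chosen in advance.

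On simulated data with 200 changed genes, 78% were recovered at a log2 change of 0.5 and 94.5% at 1 in the average, 18.5% and 84% in the difference between pretreatments, 3.5% and 78% for late against early, 0% and 58.5% at 6 h, and 32% and 87% for levels. For the late minus early difference between pretreatments none were recovered at 1 and 67% at 2. No call had the wrong sign. The simulated noise was independent between genes and arrays, without shared 0 h RNA, slide or dye effects. Recovery under such shared effects was not simulated.

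The alternatives were the software's log ratio, no background subtraction, median centring instead of loess, scaling between arrays, the series matrix, no filter and a strict filter, the mean over probes, outlier spots kept, duration as a factor, and leaving out each array. Levels hold no ratio. For levels, the settings of the software log ratio and the series matrix used the software's processed signals. The setting of scaling between arrays set medians of mean intensity equal instead of quantiles.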

Results

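Lung RNA of rats was profiled on 8 two-channel oligonucleotide arrays. Rats had received normal saline or cobalt (12.5 mg per kg body weight) for 7 days and were then held at a simulated altitude of 30000 ft for 6, 12, 24 or 48 h. Each array set the RNA of 1 pretreatment and duration against the 0 h RNA of the same pretreatment in the other channel, so that each of the 8 groups held 1 array. The series asks how the lung transcriptome responds to this hypobaric hypoxia over time and how cobalt pretreatment alters the response. Between 57.7% and 67.2% of spots were well above background in green and between 63.5% and 72.7% in red. After filtering, 24143 genes were tested, of which 12034 carried a gene name. Ratios are log2 of hypoxia over 0 h, given as the limma estimate ± SE, and p-values are adjusted by Benjamini-Hochberg. Nothing in the labels says how many animals gave each RNA, all 4 arrays of a pretreatment share the same 0 h RNA, and p-values therefore measure the spread between arrays and durations and leave out the spread of the 0 h controls.

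Averaged over both pretreatments and all durations, the highest ratio was that of Ccn3, a matricellular protein, at 2.80 ± 0.12 (6.95-fold, adjusted p = 1.6e-06). The intermediate filament gene of muscle Des rose by 2.02 ± 0.08 (adjusted p = 8.87e-07). Plvap, which forms the diaphragms of endothelial fenestrae and caveolae, fell by 1.67 on the log2 scale (SE 0.08, adjusted p = 4.14e-06). Lyve1, a hyaluronan receptor of lymphatic endothelium, had a ratio of -1.67 ± 0.15 and Tmem100, an endothelial membrane protein, one of -1.63 ± 0.17. The same sign on all 8 arrays was a condition for naming these genes and is no separate evidence.

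The other strongest increases that passed with 1 sign on all arrays were those of Slurp1 at 2.77, the activin-binding protein Fst at 2.38, osteopontin (Spp1) at 2.37, the neurotrophin receptor Ntrk2 at 2.37, the kininogens Kng1 at 2.31 and Kng2 at 2.25, and neuritin (Nrn1) at 2.28. The strongest decreases measured were those of the cytochrome oxidase subunit Cox8b at -2.04, the receptor of vasoactive intestinal peptide Vipr1 at -1.86, the corticosterone-inactivating enzyme Hsd11b2 at -1.81, the amino acid transporter Slc7a10 at -1.79, Lrrn3 at -1.43 and the neurturin receptor Gfra2 at -1.41. The 3 probes of Cox8b disagreed, with averages from -2.04 to -0.09, and their mean gave -0.75. The calls of Cox8b, Vipr1, Hsd11b2, Slc7a10 and Cyp1a1 ended with the variance trend over the mean log ratio. Cyp1a1, an enzyme of xenobiotic metabolism, had a lower fitted ratio (-2.53, and -5.47 with the software log ratio) whose size was not measured. Its hypoxia channel was well above background on 2 of the 4 saline arrays and on none of the cobalt arrays, where it was at least 2.32-fold lower than at 0 h (adjusted p = 0.000393), a bound that rests on channel levels open to dye bias.

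In all, 7712 genes passed, 3786 higher and 3926 lower. Of all genes tested, 12.8% had the same sign on all 8 arrays, where 8 independent signs would give 0.781%. Arrays of a pretreatment share the 0 h RNA, the slide and the dye orientation, so their signs are not independent. The 2982 called genes with 1 sign on all arrays are no separate evidence, because a call already favours 1 sign. Dye bias that both slides share cancels in the averaged ratio, because hypoxia RNA was in Cy5 on the saline arrays and in Cy3 on the cobalt arrays. Dye bias that differs between the slides stays in it. Of the 35 gene lists, camera called 16 with its preset correlation and 0 with an estimated correlation, and fry called 14.

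Glycolysis had the lowest camera p, with 15 of 17 measured genes higher, 1 lower and 1 not passing (16 and 1 adjusted over the list alone). The median ratio was 0.60, with enolase Eno2 at 1.24 ± 0.10, the phosphofructokinase Pfkl at 1.09 ± 0.10 and triosephosphate isomerase Tpi1 at 0.95 ± 0.09. Camera with its preset correlation placed the list above other genes (adjusted p = 7.86e-08), which did not hold with an estimated correlation (adjusted p = 0.607 with an estimated correlation). Lactate dehydrogenase Ldha rose by 0.60 ± 0.10 and the glucose transporter Slc2a1 by 0.99 ± 0.12, the latter on every array. Signs on single arrays are given after loess throughout; with median centring the cobalt response minus saline response moved to -1.71 for the glycolysis list and -1.90 for Slc2a1.

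The broader list of HIF targets went both ways. Of its 29 measured genes, 13 rose and 8 fell (13 and 9 adjusted over the list alone), the median was 0.14, and camera made no call (adjusted p = 0.246 with the preset and adjusted p = 0.714 with an estimated correlation). P4ha2, a collagen prolyl hydroxylase, rose by 1.1 ± 0.07, the mitophagy gene Bnip3 by 1.37 ± 0.12 and the haem oxygenase Hmox1 by 0.79 ± 0.14. Epas1, which encodes HIF-2 alpha, fell by 1.09 on the log2 scale (SE 0.07), the angiogenic factor Vegfa by 0.72 (SE 0.07) and endothelin Edn1 by 0.67 (SE 0.15). After loess the saline arrays gave -1.49 ± 0.09 for Vegfa (adjusted p = 1.98e-05) and the cobalt arrays 0.05 ± 0.09 (adjusted p = 0.747). Dye bias does not cancel within a pretreatment, and with median centring the difference of Vegfa between cobalt and saline turned from 1.54 to -0.24.

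Smooth muscle genes rose, with 8 of 10 higher and 2 not passing (8 adjusted over the list alone), a median of 1.16 and camera adjusted p = 4.06e-07 (adjusted p = 0.607 with an estimated correlation). Enteric actin Actg2 stood at 1.76 ± 0.08, calponin Cnn1 at 1.55 ± 0.10 and tropomyosin Tpm2 at 1.45 ± 0.09. Cardiac and skeletal muscle genes had 4 of 16 higher and none lower (4 adjusted over the list alone), a median of 0.23 and camera adjusted p = 0.00599 (adjusted p = 0.689 with an estimated correlation). Members included Tnnt2 at 1.04 ± 0.23 and Actc1 at 0.81 ± 0.15. Of 25 matrix genes, 11 rose and 1 fell (12 and 3 adjusted over the list alone), with a median of 0.22 and camera adjusted p = 0.00599 (adjusted p = 0.689 with an estimated correlation). Ccn2, a matricellular growth factor, rose by 1.79 ± 0.08, the collagen cross-linking enzyme Lox by 2.00 ± 0.19 and Col4a1 by 0.97 ± 0.07. The matrix median was -0.23 in saline, with 7 higher and 7 lower, and 0.52 in cobalt, with 12 higher and 0 lower. These values hold dye and slide, and with median centring the cobalt minus saline difference turned from 0.59 to -1.36. With the software log ratio the cardiac and skeletal muscle median was 0.51.

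Endothelial adhesion and permeability genes fell in 13 of 24 cases, rose in 2 and did not pass in 9 (13 and 2 adjusted over the list alone). The median was -0.20, with camera adjusted p = 0.00414 (adjusted p = 0.607 with an estimated correlation). The angiopoietin receptor Tek was at -0.52 ± 0.06, whereas the water channel Aqp1 was at 0.97 ± 0.08 and E-selectin (Sele) at 0.41 ± 0.06. The endothelial median was -0.50 in saline, with 14 lower and 2 higher, and 0.04 in cobalt, with 2 lower and 3 higher. Dye and slide enter both, and with median centring the cobalt minus saline difference turned from 0.56 to -1.19. The adhesion molecule Icam1 fell by 0.56 on the log2 scale (SE 0.13, adjusted p = 0.0123). T and NK cell genes fell in 13 of 20 cases with none higher (15 adjusted over the list alone), with a median of -0.39 and camera adjusted p = 5.09e-07 (adjusted p = 0.689 with an estimated correlation). Perforin (Prf1) stood at -1.12 ± 0.10, granzyme Gzma at -1.18 ± 0.14 and Nkg7 at -0.67 ± 0.08. With the software log ratio the T and NK cell median was -0.72.

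Heat shock and unfolded protein response genes rose in 19 of 26 cases with none lower (22 adjusted over the list alone), with a median of 0.38 and camera adjusted p = 1.64e-06 (adjusted p = 0.689 with an estimated correlation). The small heat shock protein Hspb1 was at 0.70 ± 0.10 and the endoplasmic reticulum chaperone Hspa5 at 0.64 ± 0.12. Lipid and cholesterol synthesis had 10 of 21 genes higher and 2 lower (10 and 2 adjusted over the list alone), with a median of 0.22 and camera adjusted p = 0.00599 (adjusted p = 0.689 with an estimated correlation), led by Sqle at 0.74 ± 0.11 and Idi1 at 0.98 ± 0.15. The lipid synthesis median was 0.36 with scaling between arrays. Antioxidant genes had 11 of 27 higher and 4 lower (12 and 4 adjusted over the list alone), with a median of 0.17 and camera adjusted p = 0.00865 (adjusted p = 0.689 with an estimated correlation). The mitochondrial superoxide dismutase Sod2 was at 0.63 ± 0.10 and the extracellular Sod3 at -0.61 ± 0.09. Respiratory chain genes had 12 of 37 higher and 2 lower (12 and 2 adjusted over the list alone), with a median of 0.04 and camera adjusted p = 0.0279 (adjusted p = 0.689 with an estimated correlation), among them Cycs at 0.46 ± 0.05 and Cox5b at 0.47 ± 0.05.

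Coagulation and acute phase genes had 8 of 24 higher and 2 lower (9 and 2 adjusted over the list alone), with a median of 0.20 and camera adjusted p = 0.0279 (adjusted p = 0.689 with an estimated correlation). Tissue factor (F3) was at 0.66 ± 0.09 and the plasminogen activator Plau at -0.63 ± 0.13. Glucocorticoid response genes had 6 of 20 higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.34 and camera adjusted p = 0.0425 (adjusted p = 0.809 with an estimated correlation). The kinase Sgk1 rose by 1.43 ± 0.10, Fkbp5, a co-chaperone of the glucocorticoid receptor, by 1.18 ± 0.28, and the metal-binding Mt1 by 1.44 ± 0.35.

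Among the epithelial lists, surfactant and type II cell genes fell in 7 of 13 cases with none higher (8 adjusted over the list alone), with a median of -0.20 and camera adjusted p = 0.00905 (adjusted p = 0.689 with an estimated correlation), as for Etv5 at -0.48 ± 0.07 and Slc34a2 at -0.31 ± 0.08. After loess the median was -0.63 in saline (11 lower, 0 higher) and 0.21 in cobalt (4 higher, 0 lower). Type I cell genes had 5 of 11 lower and 1 higher (6 and 1 adjusted over the list alone), with a median of -0.27 and camera adjusted p = 0.0319 (adjusted p = 0.689 with an estimated correlation). The water channel Aqp5 was at -0.85 ± 0.19 and Pdpn at -0.75 ± 0.18. Ciliated cell genes had 9 of 12 higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 0.43 and camera adjusted p = 0.00568 (adjusted p = 0.689 with an estimated correlation). Rsph1 was at 0.57 ± 0.08 and Tekt4 at 0.64 ± 0.10, but in saline 10 were higher and 1 lower, and in cobalt 0 were higher and 6 lower, at a median of -0.42. Cell cycle genes had 3 of 34 lower and none higher (none adjusted over the list alone), with a median of -0.20 and camera adjusted p = 0.0319 (adjusted p = 0.809 with an estimated correlation), Prc1 standing at -0.38 ± 0.10 and Mki67 at -0.46 ± 0.14. The cell cycle median was 0.21 in saline (2 higher, 0 lower) and -0.66 in cobalt (14 lower, 0 higher). Dye and slide enter the values by pretreatment. With median centring the cobalt minus saline difference turned from 0.82 to -1.52 for surfactant genes and moved from -1.71 to -3.44 for ciliated and from -0.73 to -1.91 for cell cycle genes.

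Some of these list calls rest on single arrays. The cell cycle call ended at medians of -0.12 without saline 6 h, -0.13 without saline 24 h, -0.16 without cobalt 12 h and -0.14 without cobalt 24 h, and its median was -0.30 without saline 48 h, -0.34 with the software log ratio, -0.38 with median centring and -0.31 with scaling between arrays. The glucocorticoid call ended at 0.22 without saline 6 h, 0.27 without saline 12 h, 0.23 without cobalt 6 h and 0.32 without cobalt 24 h. The coagulation call ended at 0.16 without saline 6 h and 0.15 without cobalt 6 h, and the type I cell call at -0.23 without cobalt 6 h and -0.28 without cobalt 24 h. The respiratory chain call ended at 0.017 without saline 48 h, 0.053 without cobalt 24 h and 0.038 without cobalt 48 h, and its median was 0.071 without saline 12 h and 0.090 without cobalt 6 h. Median centring ended the calls of the antioxidant (0.16), coagulation (0.21), glucocorticoid (0.17), respiratory chain (0.063), surfactant (-0.16) and type I cell (-0.36) lists. The strict filter ended those of the cell cycle (-0.24), coagulation (0.14), glucocorticoid (0.31) and type I cell (-0.27) lists, and the mean over probes that of the glucocorticoid list (0.29). The software log ratio and the series matrix ended the calls of type I cells (-0.33 in both) and of the respiratory chain (0.063 and 0.061). Scaling between arrays ended the surfactant call (-0.15). Duration as a factor, which pairs the saline and cobalt arrays of a duration, ended the respiratory chain call at the same median. Of the 16 calls, 9 held in every alternative.

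The other lists were not called, with camera adjusted p from 0.0529 for alveolar macrophages to 0.951 for cytokines. Their medians were 0.24 for alveolar macrophage genes, 0.24 for club and secretory cell genes, 0.12 for neutrophil genes, -0.16 for B and plasma cell genes, 0.18 for mast cell and eosinophil genes, 0.09 for erythroid genes, 0.04 for platelet genes, 0.09 for adipocyte genes and 0.04 for genes of neighbouring tissues such as thyroid and oesophagus. They were 0.07 for metallothionein and metal handling, 0.03 for alveolar ion and water transport, 0.01 for inflammatory cytokines, -0.09 for interferon-stimulated genes, 0.07 for the circadian clock, 0.03 for fatty acid oxidation, 0.04 for ribosomal proteins, -0.21 for vasoactive genes and 0.08 for immediate early genes. Median and camera direction differed in sign for inflammatory cytokines and for mast cells, and the mean of the ribosomal list was -0.00. The chemokine Ccl2 rose by 1.36 ± 0.10 within the cytokine list, in which Ccl5 fell by 0.82 on the log2 scale. Scnn1a, a subunit of the epithelial sodium channel, gave 0.40 ± 0.17 (adjusted p = 0.0896), passing with 0.52 when the saline 48 h array was left out. Per1 at 0.26 ± 0.14, Bmal1 at 0.38 ± 0.22, Dbp at -0.33 ± 0.26, Nr1d1 at -0.29 ± 0.25, Alas2 at -0.24 ± 0.28 and Sftpc at -0.19 ± 0.08 did not pass.

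**Figure D1:**
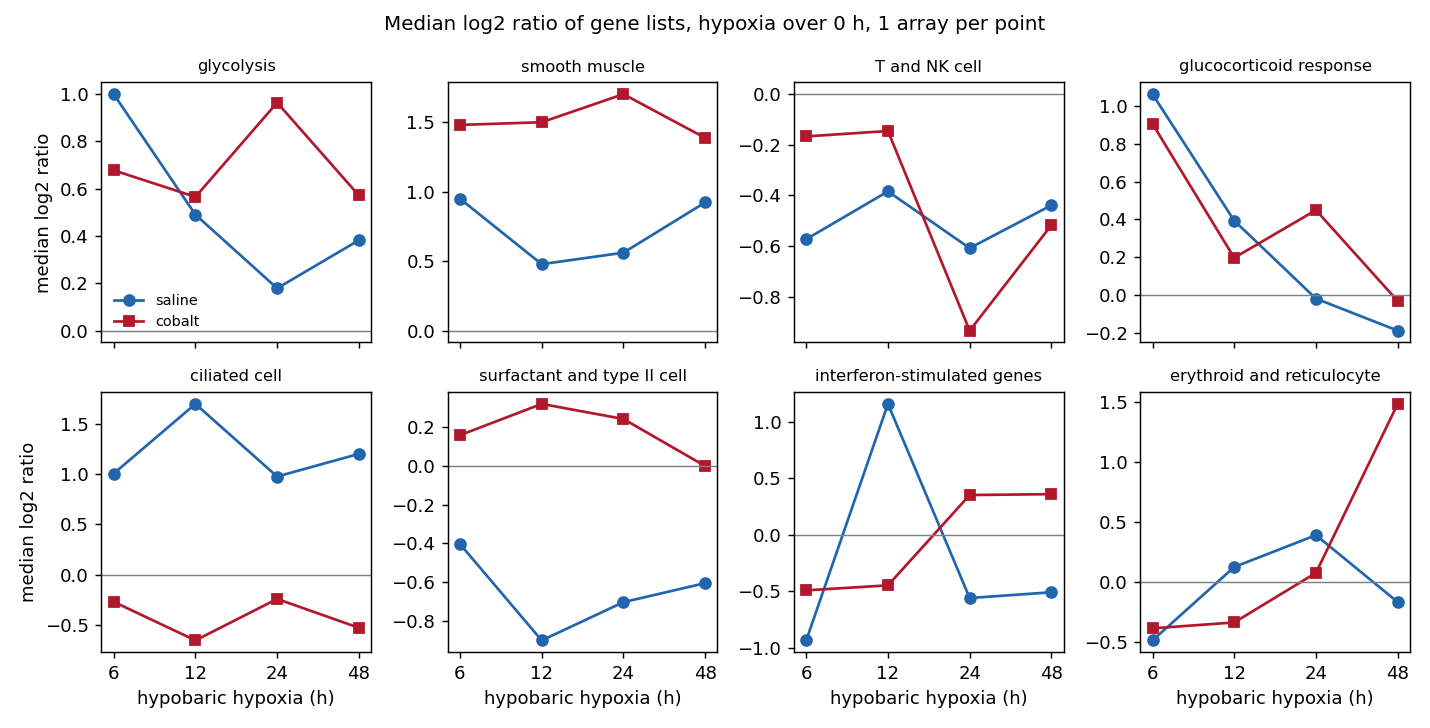
Median log2 ratio of hypoxia over 0 h (vertical axis) for 8 gene lists against hours of hypoxia (horizontal axis, durations evenly spaced), with 1 array per point, saline in blue circles and cobalt in red squares. After loess, glycolysis and smooth muscle lie above 0 on all 8 arrays, whereas the ciliated list is above 0 on the 4 saline arrays and below 0 on the 4 cobalt arrays.

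Taken by pretreatment, 9685 genes changed in saline-treated rats, 5257 higher and 4428 lower, and 5027 in cobalt-treated rats, 2061 higher and 2966 lower. The calls shared a direction for 721 higher genes, where independent lists would share 449, and for 699 lower genes, where they would share 544. A further 719 genes were higher in saline and lower in cobalt (646 for independent lists) and 426 the reverse (378). Both calls of a gene use the same estimate of its spread, which favours shared calls in either direction. In saline the HIF list held 11 higher and 7 lower genes with a median of 0.08, and in cobalt 8 higher and 3 lower with a median of 0.09. Within a pretreatment the dye bias does not cancel. Setting the median of all probe spots of an array to 0 instead of loess left the medians of the tested genes at 0.23 to 0.34 in saline and -0.53 to -0.45 in cobalt. It moved the share of higher genes from 54.3% to 84.1% in saline and from 41.0% to 25.2% in cobalt. The cobalt counts fell to 1290 and 1756 without the 6 h array, 1060 and 1396 without 12 h, 1008 and 1265 without 24 h, and the lower genes to 1882 without 48 h.

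The comparison of the cobalt response with the saline response asks which genes respond otherwise after cobalt. The ciliated list separated the pretreatments most, with 11 of 12 genes lower in the cobalt response than in the saline response (11 adjusted over the list alone) and none higher. Its median difference was -1.71, with camera adjusted p = 1.42e-06 (adjusted p = 0.422 with an estimated correlation), and the radial spoke genes Rsph1 and Rsph9 differed by -2.04 ± 0.16 and -2.00 ± 0.16. Club and secretory cell genes went the same way in 3 of 10 cases with none higher (5 adjusted over the list alone), with a median of -1.07 and camera adjusted p = 0.0154 (adjusted p = 0.422 with an estimated correlation). Cyp2f4, a cytochrome P450 of club cells, differed by -3.29 ± 0.33 and the secretoglobins Scgb3a2 and Scgb1a1 by -1.90 ± 0.18 and -1.74 ± 0.26. Surfactant and type II cell genes went the opposite way in 8 of 13 cases with none lower (8 adjusted over the list alone), with a median of 0.82 and camera adjusted p = 7.81e-06 (adjusted p = 0.422 with an estimated correlation), as for Sftpa1 at 1.40 ± 0.13 and Sftpb at 1.85 ± 0.24.

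Cell cycle genes were lower in the cobalt response in 16 of 34 cases with none higher (22 adjusted over the list alone), with a median of -0.73 and camera adjusted p = 6.82e-05 (adjusted p = 0.884 with an estimated correlation), including Ccne1 at -1.80 ± 0.37 and Pcna at -0.75 ± 0.17. Smooth muscle genes were higher in 8 of 10 cases (9 adjusted over the list alone, median 0.62, camera adjusted p = 0.000107, adjusted p = 0.422 with an estimated correlation). Members included Myh11 at 1.64 ± 0.25. Endothelial genes had 12 of 24 higher and 2 lower (13 and 2 adjusted over the list alone, median 0.56, camera adjusted p = 0.0003, adjusted p = 0.422 with an estimated correlation). Members included Vegfa at 1.54 ± 0.13 and Aqp1 at 1.64 ± 0.16. Matrix genes had 8 of 25 higher and 2 lower (11 and 2 adjusted over the list alone, median 0.59, camera adjusted p = 0.000341, adjusted p = 0.422 with an estimated correlation). Members included the metalloproteinase Mmp14 at 2.21 ± 0.23. Immediate early genes had 7 of 23 higher (9 adjusted over the list alone, median 0.41, camera adjusted p = 0.00165, adjusted p = 0.884 with an estimated correlation), lipid synthesis 6 of 21 (6 adjusted over the list alone, median 0.32, camera adjusted p = 0.00378, adjusted p = 0.884 with an estimated correlation) and vasoactive genes 11 of 29 with 2 lower (14 and 3 adjusted over the list alone, median 0.45, camera adjusted p = 0.0168, adjusted p = 0.422 with an estimated correlation). With median centring instead of loess the medians of the surfactant, smooth muscle, endothelial, matrix, immediate early, lipid and vasoactive lists turned below 0, and the club (-2.75) and cell cycle (-1.91) lists lost their calls. The vasoactive call also ended with no filter (0.35). Of the 10 calls, only that of the ciliated list held in every alternative, at -3.44 with median centring. Median centring lowered the medians of all 10 lists, so it could turn lists above 0 but not lists below 0. That the ciliated list kept its sign there is no separate evidence. The median was -1.29 for cell cycle and 0.49 for lipid synthesis with the software log ratio, and 1.06 for smooth muscle with scaling between arrays.

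Among single genes whose 4 cobalt and 4 saline arrays did not overlap, the highest differences after Sftpc were those of the interferon-induced membrane protein Bst2 at 3.0 ± 0.27, the desaturase Scd at 2.66, the haematopoietic signalling gene Hcls1 at 2.64, elastin (Eln) at 2.52, Lrrc8a at 2.50, the haemoglobin gene Hba-a3 at 2.50, Spon2 at 2.48 and Sox4 at 2.29. The level of Bst2 over both channels was lower in cobalt, so a difference between the 0 h RNAs may enter its ratio. The lowest were those of the thioesterase Acot1 at -3.34 ± 0.73, Cyp2f4, the airway secretory gene Agr2 at -3.27, Cyp2a3 at -2.71, Crym at -2.64, the chemokines Ccl19 at -2.54 and Cxcl10 at -2.40, Cd24 at -2.43, Capsl at -2.43 and the monooxygenase Fmo2 at -2.38. Sftpc, which encodes surfactant protein C, gave 3.21 ± 0.16. Its probe and that of Hba-a3 were saturated on all 8 arrays, and the other probe of Sftpc gave 0.56, so that the size was not measured. Saturated signals were nearly all red, 120 to 232 per array against at most 2 in green. Red was hypoxia on the saline arrays and 0 h on the cobalt arrays. A clipped red signal would therefore raise this difference, so the direction of both genes stays open too. The other probe of Lrrc8a gave 0.53. Cyp1a1 also passed, but its size was not measured, since its hypoxia channel was not well above background on any cobalt array, and its call ended with the software log ratio (1.41). With the mean over probes Lrrc8a gave 1.51 and Sftpc 1.89, and with the software log ratio Lrrc8a gave 3.93. Median centring ended the calls of Bst2 (0.47) and Sox4 (0.34) and moved Sftpc to 0.43, Scd to 1.00, Hcls1 to 1.02, Eln to 1.15 and Spon2 to 0.69. It moved Cyp2f4 to -5.27, Fmo2 to -4.70, Cd24 to -4.64, Crym to -4.27, Ccl19 to -4.15 and Capsl to -3.94. Cxcl10 lost its call without any single array except saline 6 h or saline 24 h, its difference falling to -1.65 without saline 12 h. Per1 differed by 1.18 ± 0.28 (adjusted p = 0.0112) and Nr1d1 by 1.58 ± 0.49 (adjusted p = 0.0354), the arrays of both overlapping between the pretreatments and the latter losing its call when any array but saline 48 h or cobalt 6 h was left out, with median centring (0.77) and with the software log ratio (2.28). Among the genes named in advance, Hmox1 (0.62 ± 0.28, passing with 0.81 without saline 6 h), Slc2a1 (-0.02 ± 0.23), Ldha (0.21 ± 0.21), Edn1 (-0.61 ± 0.30), Mt1 (-0.99 ± 0.71) and Fkbp5 (-1.11 ± 0.56) did not pass.

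In all, 7269 genes differed, 3065 higher and 4204 lower, and 6507 of these had arrays that did not overlap, which a call already favours. Of all genes tested, 31.9% had arrays that did not overlap, where chance gives 2.86%, and slide and dye enter this share. The difference holds the dye bias of both orientations, both 0 h controls and the slide, since all saline arrays lay on slide 1 with hypoxia in Cy5 and all cobalt arrays on slide 2 with hypoxia in Cy3, so that batch, dye and pretreatment cannot be told apart. Median centring instead of loess lowered the share of higher genes from 42.2% to 21.5% and turned the sign of Vegfa, Per1 and Hba-a3.

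**Figure D2:**
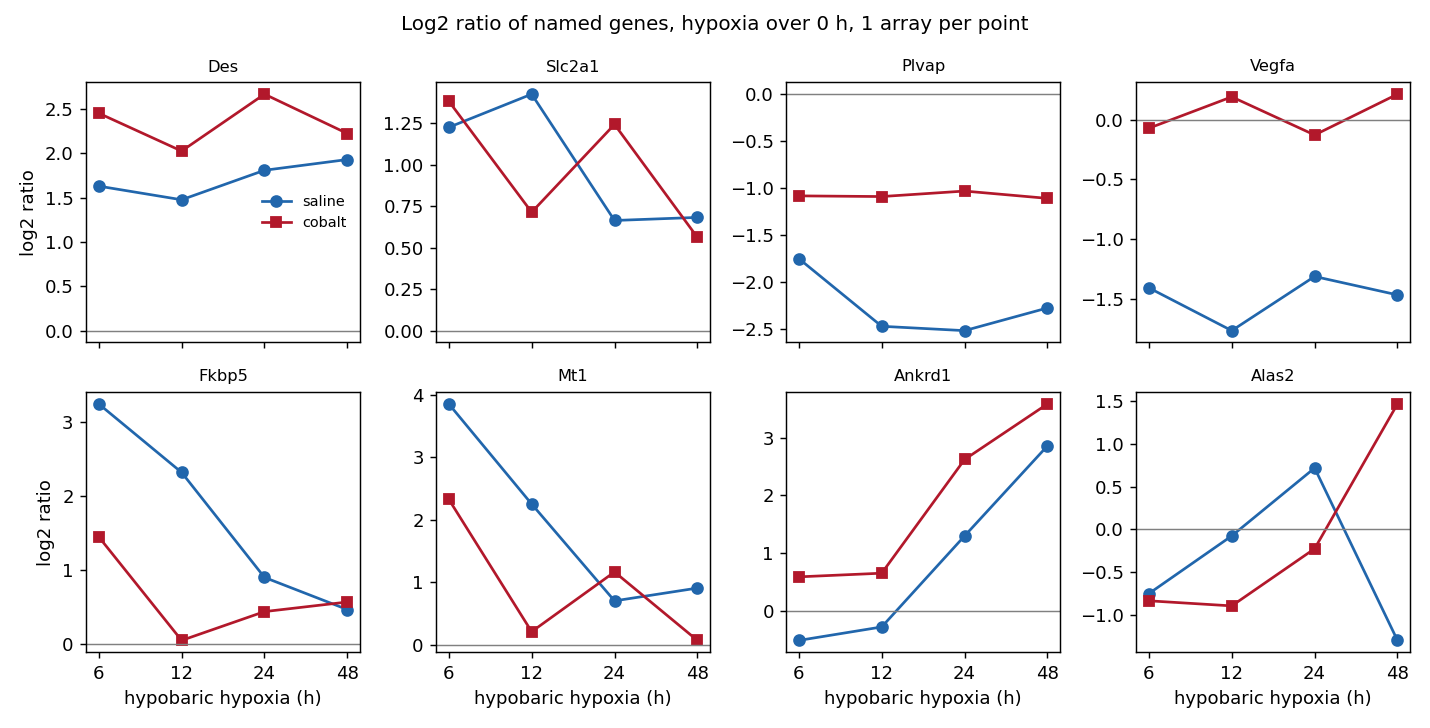
Log2 ratio of hypoxia over 0 h (vertical axis) for 8 genes against hours of hypoxia (horizontal axis, durations evenly spaced), with 1 array per point, saline in blue circles and cobalt in red squares. After loess, Des and Slc2a1 lie above 0 and Plvap below 0 on all 8 arrays, Vegfa lies between -1.76 and -1.31 on the saline arrays and between -0.13 and 0.21 on the cobalt arrays, and Ankrd1 is highest at 48 h in both pretreatments.

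Dye bias, slide and control effects that are constant over the arrays of a pretreatment cancel in differences between durations, and dye bias that varies from array to array does not. A moderated F test over the 4 durations passed 2 genes, Ankrd1 and Gal, which were chosen for naming after their values were seen. Ankrd1, a stress-induced nuclear cofactor of muscle and endothelium, stood at 0.03 ± 0.13 at 6 h, 0.18 ± 0.13 at 12 h, 1.96 ± 0.13 at 24 h and 3.23 ± 0.13 at 48 h. Gal, the precursor of the neuropeptide galanin, ran the other way, from 3.25 ± 0.12 at 6 h over 2.31 ± 0.12 and 0.78 ± 0.12 to -0.28 ± 0.12 at 48 h. The F test was left with 1 gene without saline 6 h, 6 without cobalt 12 h and 0 without any other single array. It passed 0 with median centring and 0 with scaling between arrays.

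With 24 and 48 h set against 6 and 12 h, limma called 0 genes, while 3098 had an unadjusted p under 0.05 and the lowest adjusted p was 0.278. The lowest p-values, none passing, were those of the aldehyde oxidase Aox3 at -0.66 ± 0.08, Ankrd1 at 2.49 ± 0.32 and Gal at -2.53 ± 0.35. Leaving out cobalt 12 h gave 1 higher and 2 lower genes. No single member passed in any list. Glucocorticoid response genes had a median of -0.65 (4 lower adjusted over the list alone, camera adjusted p = 1.26e-05, adjusted p = 0.83 with an estimated correlation), Cdkn1a standing at -1.17 ± 0.29 and Cebpb at -0.55 ± 0.14. Matrix genes had a median of 0.24 (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 4.88e-05, adjusted p = 0.321 with an estimated correlation). Members included Fbn1 at 1.22 ± 0.21 and Col3a1 at 0.77 ± 0.17. Erythroid genes had a median of 0.73 (0 adjusted over the list alone, camera adjusted p = 4.88e-05, adjusted p = 0.83 with an estimated correlation). Members included the haemoglobin chaperone Ahsp at 1.53 ± 0.50 and the anion exchanger Slc4a1 at 1.64 ± 0.59. The erythroid median was 1.48 on the cobalt 48 h array against -0.48 to 0.39 on the other 7, and the late median was 0.31 without that array. The other lists called by camera were respiratory chain (median 0.12, adjusted p = 0.321 with an estimated correlation), and heat shock (-0.28), immediate early (-0.28), T and NK cell (-0.20), lipid synthesis (0.16), smooth muscle (0.25) and B cell genes (-0.40), each at adjusted p = 0.83 with an estimated correlation. Calls ended for B cell genes without saline 12 h (-0.14) or 24 h (-0.16), for T and NK cell genes without saline 12 h (-0.24), cobalt 12 h (-0.092) or cobalt 24 h (-0.060) and for heat shock genes without saline 12 h (-0.13). They also ended for lipid synthesis without saline 6 h (0.11), 12 h (0.12) or 48 h (0.040) and for smooth muscle without saline 12 h (0.21), saline 48 h (0.18) or cobalt 24 h (0.18). The strict filter ended the B cell call (-0.43), and the software log ratio, the series matrix and the trend over the mean log ratio each ended the smooth muscle call. Of the 10 calls, 5 held in every alternative. Fry called 0 lists (lowest adjusted p = 0.0901). Medians moved for T and NK cell genes without saline 6 h (-0.35), lipid synthesis without cobalt 12 h (0.28) and immediate early genes without saline 24 h (-0.50) or 48 h (-0.18). With scaling between arrays they were -0.40 for T and NK cell, -0.18 for heat shock and 0.46 for smooth muscle genes, and with the software log ratio -0.32 for T and NK cell genes.

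At single durations, averaged over both pretreatments, 988 genes were higher and 883 lower at 6 h. That 6 h gave more calls than the other durations depends on the scaling. With median centring 12 h gave 1823 and 3026 against 1055 and 1026 at 6 h, and with scaling between arrays 24 h gave 551 and 602 against 520 and 452. Glucocorticoid response genes rose in 13 of 20 cases at 6 h (16 adjusted over the list alone, median 0.96, camera adjusted p = 1.47e-08, adjusted p = 0.746 with an estimated correlation). Sgk1 rose by 1.28 ± 0.10, the cell cycle inhibitor Cdkn1a by 1.92 ± 0.15, Mt1 by 3.09 ± 0.37 and Fkbp5 by 2.34 ± 0.38, while Mt1 at 48 h was 0.49 ± 0.37 and did not pass. Coagulation and acute phase genes had 5 of 24 higher and 1 lower (9 and 1 adjusted over the list alone, median 0.46, camera adjusted p = 0.00018, adjusted p = 0.746 with an estimated correlation). Members included Orm1 at 1.65 ± 0.11 and Hp at 2.07 ± 0.29. T and NK cell genes had 6 of 20 lower (9 adjusted over the list alone, median -0.28, camera adjusted p = 7.44e-05, adjusted p = 0.746 with an estimated correlation). Members included granzyme Gzmb at -1.63 ± 0.17 and Gzma at -1.61 ± 0.18. Fry called 0 lists at 6 h and at 12 h, and 4 each at 24 and 48 h. Counts were 450 higher and 479 lower at 12 h, 186 and 153 at 24 h, and 188 and 177 at 48 h, where matrix genes had 8 of 25 members higher with a median of 0.67 (camera adjusted p = 1.4e-11, adjusted p = 0.386 with an estimated correlation).

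Each duration rests on 2 arrays, and the counts of higher and lower genes depended on them. At 6 h they were 46 and 11 without saline 6 h, 68 and 31 without cobalt 6 h, 419 and 337 without saline 48 h and 425 and 345 without cobalt 48 h, and 577 genes were lower without saline 24 h. At 12 h they were 10 and 2 without saline 12 h but 467 and 368 without cobalt 12 h, 180 and 175 without saline 24 h, 185 and 183 without cobalt 24 h, 71 and 51 without saline 48 h and 71 and 56 without cobalt 48 h. At 24 h they were 18 and 5 without saline 24 h, 6 and 0 without cobalt 24 h, 69 and 32 without saline 48 h and 76 and 34 without cobalt 48 h, and the lower genes numbered 239 without saline 12 h and 243 without cobalt 12 h. At 48 h they were 13 and 1 without saline 48 h, 11 and 1 without cobalt 48 h, 88 and 63 without saline 24 h and 97 and 69 without cobalt 24 h. Median centring instead of loess moved the share of higher genes from 48.4% to 37.6% at 12 h and from 54.9% to 29.0% at 24 h.

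In single arrays, which have no replicate, between 435 genes (cobalt 48 h) and 1664 genes (saline 12 h) stood at 2-fold or more. At 6 h, 135 genes were at least 2-fold higher in both pretreatments, where independent arrays would share 10.3, 94 at least 2-fold lower (7.31) and 32 opposite (17.7). These counts were 73 (10.6), 37 (5.96) and 69 (15.9) at 12 h, 79 (4.73), 41 (3.30) and 16 (8.16) at 24 h, and 63 (6.23), 30 (2.22) and 33 (7.53) at 48 h. Ratios across all genes correlated with r from -0.0983 to 0.269 after loess and from -0.562 to -0.135 with median centring over the 16 pairs of a saline and a cobalt array, genes not being independent replicates.

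Whether the change from early to late durations differed between cobalt and saline was the 1 test of cobalt from which dye, slide and control effects that are constant over the arrays of a pretreatment cancel. limma called 0 genes, with 1315 at an unadjusted p under 0.05 and a lowest adjusted p of 0.706. The lowest p-values, none passing, were those of Akap5 at -1.78 ± 0.25, the interferon-induced Ifitm3 at 1.54 and Nedd9 at -1.30. Leaving out saline 6 h gave 32 higher genes and leaving out cobalt 12 h gave 2 lower genes. Camera called 19 of 35 lists and none with an estimated correlation, and 5 of the 19 calls held in every alternative. Fry called 0 lists (lowest adjusted p = 0.751). Interferon-stimulated genes had the lowest camera p, with a median of 1.15 (0 of 28 adjusted over the list alone, camera adjusted p = 2.02e-11, adjusted p = 0.57 with an estimated correlation), Ifit1 standing at 3.05 ± 1.02 and Irf1 at 0.74 ± 0.22. The interferon median was 1.16 on the saline 12 h array against -0.94, -0.56 and -0.51 on the other saline arrays, and the difference was 0.30 without saline 12 h and 2.20 without saline 6 h. Neutrophil genes had a median of 1.05 (6 of 13 adjusted over the list alone, camera adjusted p = 2.71e-07, adjusted p = 0.57 with an estimated correlation). Members included the calprotectin gene S100a8 at 3.01 ± 0.76. Lipid synthesis had a median of -0.55 (2 of 21 adjusted over the list alone, camera adjusted p = 9.55e-07, adjusted p = 0.57 with an estimated correlation). Members included Scd at -1.52 ± 0.37. Erythroid genes had a median of 1.00 (0 of 16 adjusted over the list alone, camera adjusted p = 0.000144, adjusted p = 0.57 with an estimated correlation). The erythroid call ended without cobalt 48 h (0.16), and its median was 0.66 without saline 12 h, 0.50 without saline 48 h and 1.82 without cobalt 24 h. The neutrophil median was 0.64 without cobalt 24 h and the lipid synthesis median -0.28 without cobalt 12 h. The neutrophil median was 1.91 with the software log ratio and 0.63 with no filter, and that of lipid synthesis -0.36 with scaling between arrays. Median centring moved the HIF list from 0.12 to 0.21 (adjusted p = 0.57 with an estimated correlation) and ended the call of immediate early genes (-0.26 to -0.12, adjusted p = 0.629 with an estimated correlation). The HIF call held there but ended with the software log ratio (0.14) and the mean over probes (0.11). It also ended without most single arrays, as without cobalt 24 h (0.068), and its median was 0.37 without cobalt 6 h. The immediate early call also ended with the software log ratio (-0.31) and scaling between arrays (-0.19). Without most single arrays it ended too, as without saline 24 h (-0.030). Processing and single arrays therefore both enter this test.

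Levels averaged over both channels were compared between the pretreatments, each level joining hypoxia and 0 h RNA. Cell cycle genes were higher in cobalt in 18 of 34 cases and lower in 1 (19 and 1 adjusted over the list alone, median 0.48, camera adjusted p = 0.00206, adjusted p = 0.842 with an estimated correlation). Members included Prc1 at 0.94 ± 0.10 and the helicase subunit Mcm2 at 0.82 ± 0.11. Matrix genes were higher in 9 of 25 cases (9 adjusted over the list alone, median 0.24, camera adjusted p = 0.0265, adjusted p = 0.842 with an estimated correlation). Members included Timp3 at 1.93 ± 0.16 and Col4a2 at 1.55 ± 0.14. Smooth muscle genes were higher in 7 of 10 cases (7 adjusted over the list alone, median 0.42, camera adjusted p = 0.0265, adjusted p = 0.842 with an estimated correlation). Interferon-stimulated genes were lower in 8 of 28 cases and higher in 1 (7 and 1 adjusted over the list alone, median -0.37, camera adjusted p = 0.0416, adjusted p = 0.842 with an estimated correlation), Bst2 being at -1.96 ± 0.10. The cobalt response minus saline response had the opposite sign for cell cycle genes (-0.73) and for Bst2 (3.0). A difference between the 0 h RNAs may therefore enter both responses. The interferon call ended without saline 12 h (-0.15), cobalt 6 h (-0.29) or cobalt 12 h (-0.29), and with no background subtraction (-0.37). With the mean over probes the calls of the matrix (0.18), smooth muscle (0.32) and interferon (-0.30) lists ended. The matrix call also ended (0.070) in the setting of scaling between arrays, which for levels equalizes medians instead of quantiles of mean intensity. The cell cycle call held in every alternative.

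The highest level differences were those of the small GTPase Rab15 at 4.08 ± 0.15, the ribosomal protein gene Rps15 at 2.66, the basement membrane gene Nid1 at 2.63, Fam13a at 2.49, Fnip2 at 2.47, Brd1 at 2.23, Klf13 at 2.13, Foxe1 at 1.98, Man2a1 at 1.97 and Timp3. The lowest were those of the kinesin gene Kif19 at -3.81 ± 0.28, Rbm38 at -3.70, Dlk1 at -3.52, Tac4 at -3.17, Ache at -2.40, Or1f26 at -2.36 and gastrin (Gast) at -2.34. The interferon gene Ifna4, the odorant receptor gene Or10s1 and Cyp11b3 were also lower in cobalt, but were not well above background on any cobalt array, so that the size was not measured. It was -3.43, -2.90 and -2.34 in the fit and -6.45, -6.46 and -5.16 with the software's processed signals, which moved Tac4 to -4.82. The probes of Kif19, Rbm38, Dlk1, Ifna4, Tac4, Or10s1 and Cyp11b3 hold runs of 7 to 12 bases of the telomere repeat. With the mean over a gene's probes the level difference was 2.50 for Rab15, 1.72 for Rps15, 0.99 for Nid1, 0.65 for Brd1 and 1.02 for Man2a1. In all, 5148 genes were higher in cobalt and 5749 lower, 9243 of them with arrays that did not overlap, which a call already favours. Of all genes tested, 41.2% had levels that did not overlap, where chance gives 2.86%. Each pretreatment lay on a slide of its own, so that slide and pretreatment cannot be told apart in these levels.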

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

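The tests of saturated signals and of airway tissue were chosen after the results they measure were seen; the others were chosen before.

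The response differed between cobalt and saline for 7269 genes by the test of the difference itself. The difference of a gene's 2 probes correlated with r = 0.549 (0.526 to 0.572, 3475 genes), against 0.693 for the averaged response and 0.631 for late against early, so that part of it is shared by probes, but probes of a gene may share a dye effect and gene-specific dye bias stays open. Probe base composition and mean intensity together explained 5.90% of the variance of the difference, against 0.754% for the average. Their shares were not separated, and both stay open. Of the called genes, 2.02% (147) had a saturated channel, a share that did not decide the test. Saturation stays open for those 147, and the other called genes had no saturated channel by this count. Of the 35 splits of the 8 arrays, 1, the real one, gave as many genes, the highest other giving 1. The real split is also the split by slide, scan, dye and 0 h RNA. A difference in response to hypoxia after cobalt cannot be told apart from these. The arrays of a pretreatment share them, so the splits do not exclude a chance difference between the 0 h RNAs.

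The ciliated cell list differed between the pretreatments by a median of -1.71 and the club and secretory cell list by -1.07, each called by the test of the difference (adjusted p = 0.422 with an estimated correlation for both), and by -3.44 and -2.75 with median centring, where the club call ended. The ciliated medians were 1.00, 1.70, 0.98 and 1.20 on the saline arrays and -0.27, -0.65, -0.24 and -0.53 on the cobalt arrays. As a hypothesis, more airway tissue in some RNA samples may account for both; the club list moved in the same direction (-1.07), a value seen before the explanation was written, so that it does not test it independently. The other probes of 3 ciliated genes had a median of -0.556, lower in size than the -1.71 over the probes used for the whole list. They were not set against the used probes of the same 3 genes, and by the rule of choice they were dimmer. These 3 probes cannot settle dye bias. The share of airway in each sample and a response of airway cells to cobalt were not measured and stay open.

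The surfactant and type II cell list differed by a median of 0.82, by the test of the difference (adjusted p = 0.422 with an estimated correlation), and by -1.52 with median centring. Sftpc differed by 3.21, by the test of the difference, on a probe saturated on all 8 arrays, and its other probe gave 0.56, so that the size was not measured. Clipping of the red signal would raise this difference, so its direction stays open too.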

How the results depend on the processing

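The variance trend over the mean log ratio was chosen after the result was seen; the other settings were planned. Over the alternatives, 2064 of 2137 values of single genes and 2945 of 3325 list values kept their direction and side of the threshold. Of the others, 25 gene values were weaker, 16 stronger, 3 reversed and 29 moved, and 115 list values were weaker, 95 stronger, 9 reversed and 161 moved. Here reversed is a turned sign of a called value, and moved a turned sign of a value not called. The cause was not tested for any value below.

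Among called values, median centring instead of loess turned the most signs (3 genes and 7 lists). Among values not called, it turned the signs of 7 genes and 18 lists, and leaving out saline 6 h those of 26 lists. With median centring, all-gene medians were 0.23 to 0.34 on the saline arrays and -0.45 to -0.53 on the cobalt arrays, against -0.03 to 0.03 after loess. Higher and lower genes numbered 11993 and 2272 in saline and 4902 and 14521 in cobalt, lower genes 5944 in the average and 14959 in the difference between pretreatments, and 1823 and 3026 genes were called at 12 h, with 643 lower at 24 h and 346 lower at 48 h and 0 genes differing between durations. In the difference Hba-a3 turned to -0.26, Per1 to -0.24 and Vegfa to -0.24, and the list medians turned to -1.19 (endothelial), -1.36 (matrix), -0.87 (immediate early), -1.12 (lipid synthesis), -0.75 (smooth muscle), -1.52 (surfactant) and -1.16 (vasoactive). Of the 7269 genes called in the difference, 4067 were called in the same direction and 1860 in the opposite one, and 2605 had the opposite sign. Levels do not depend on this setting by construction. The all-gene medians shifted upward on the saline arrays, with hypoxia RNA in Cy5, and downward on the cobalt arrays, with hypoxia RNA in Cy3. Both shifts run toward red, as a dye bias left in by median centring would. Its share in the turned signs was not tested.

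Scaling between arrays gave 520 and 452 genes at 6 h, 101 and 84 at 12 h, 551 and 602 at 24 h, 48 and 45 at 48 h, and 0 for any duration. The software log ratio gave 693 and 797 at 12 h and 302 and 247 at 24 h, the series matrix 683 and 784, and 303 and 245. The trend over the mean log ratio gave 0 and 0 at 12 h, 0 and 0 at 24 h, 1 and 0 at 48 h and 0 for any duration. Duration as a factor, which pairs the saline and cobalt arrays of a duration, gave 3101 and 4127 genes in the difference between pretreatments, 4743 and 5383 in the level, and 1 and 1 late against early.

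Leaving out each array gave, lowest to highest, 2772 to 3654 higher and 2738 to 3872 lower genes in the average, 4080 to 5155 and 3474 to 4397 in saline, 1008 to 2323 and 1265 to 3275 in cobalt, 2224 to 3162 and 2974 to 4113 in the difference, 4243 to 5352 and 4663 to 6055 in the level, 46 to 1125 and 11 to 1133 at 6 h, 10 to 467 and 2 to 422 at 12 h, 6 to 252 and 0 to 243 at 24 h, 11 to 253 and 1 to 249 at 48 h, 0 to 6 for any duration, 0 to 1 and 0 to 2 late against early, and 0 to 32 and 0 to 2 for its difference between pretreatments. In that last comparison the antioxidant and NRF2 list median ran from -0.024 (without saline 6 h) to 0.26 and the platelet and megakaryocyte list median from -0.074 (without saline 48 h) to 0.99. A duration left with 1 array is assumed to vary like the others.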

Other observations

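The tests of the telomere repeat, and the splits for late against early and for its difference between pretreatments, were chosen after the results were seen; the other splits were chosen before.

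Interferon-stimulated genes had a median of 1.16 on the saline 12 h array, against medians from -0.94 to 0.36 on the other 7 arrays. It lay at percentile 100 of 10000 random lists of that array, and 11 other probes of 9 of the genes had a median of 0.49. Both values were computed after the pattern was seen. Erythroid genes had a median of 1.48 on the cobalt 48 h array, against -0.48 to 0.39 on the other 7.

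Of the genes lowest in level in cobalt, Kif19, Rbm38, Dlk1, Ifna4 and Or10s1 share 1 ratio pattern over the saline arrays, Kif19 standing at -1.92, 1.85, 1.36 and -0.07. The 16 genes within 0.5 log2 of Kif19 on all 4 saline arrays all had a probe with a run of 6 or more bases of the telomere repeat CCCTAA, as do 4.27% of all genes, and were all lower in level in cobalt (median -3.28). The repeat was found by reading these probes and searching many motifs, so the test used the other probes: the 72 with a run of 8 or more had a median level difference of -0.55, against -0.10 for 226 probes with a run of 7 and -0.00 for 27224 with 5 or fewer, and against 0.02 for the repeat read backward and -0.02 for the opposite strand. The probes of Tac4 (run of 8) and Cyp11b3 (run of 7), also among the lowest in level, stayed in these sets. The other probes are therefore not a fully independent set. As a hypothesis, labelled material with this repeat may have bound these probes on slide 1 (-0.55), so that their values may not report the named genes. No biological explanation was tested.

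For the average over both pretreatments, 1 of 35 splits, the real one with 7712 genes, gave as many (highest other 0). For the level with 10897 genes, 1 of 35 did (highest other 0). In both cases the real split is also the split by slide and scan. The arrays of a pretreatment also share the 0 h RNA, so a chance difference between the 0 h RNAs could give the same result. The splits therefore do not exclude chance. For late against early, limma called 0 genes (3098 at an unadjusted p under 0.05), and 0 genes in the difference of that contrast between pretreatments (1315 at an unadjusted p under 0.05). Any split gives at least 0 genes, so that the 34 of 34 splits (highest other 5) and the 18 of 18 splits (highest other 4) say nothing about chance.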
